A study of Mus musculus with 15 samples.

How the data were processed

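Total RNA of whole kidney was extracted with a mirVana kit and made into libraries with a TruSeq Stranded mRNA kit, per the labels' protocols. The values used are the FPKM per gene that the authors deposited in 1 table for the whole series (fragments per kilobase of transcript, scaled to the mapped reads of each library), with 17832 genes and 15 libraries. Per the submitters' processing notes, Trimmomatic, HISAT2, HTSeq and Cufflinks were used with genome build GRCm39; their versions, settings and the strand setting of the counting are not given in the sources used here. The gene annotation at hand was of another assembly, GRCm38, so no coordinates are given, and it was used by gene symbol only, for which genes overlap or neighbour each other. Of the genes, 17221 (96.6%) were matched by symbol. Pathway sets came from the annotation columns of the deposited table.

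Each gene's FPKM values were whole multiples of what 1 read is worth, so the number of reads per gene and library could be recovered. This held for 100% of the values at a relative tolerance of 1e-08, and the step was tested on simulated data of 1467 genes, all of which came out exactly. Reads per library are sums of these numbers over genes. They were used for depth, for the noise between libraries and for thinning, and a count model was not used. A boundary of 5 M reads defined the high-read set (8 libraries, mean 15.6 M) and the low-read set (7 libraries, mean 1.90 M). Intervals from read numbers and floors of 3 reads cover counting error only, since reads without molecular identifiers are not independent molecules.

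Tests used limma with an intensity trend on log2(FPKM + 1) over the 12869 genes with a mean of at least 0.5 FPKM over the libraries, in 1 fit of all libraries with 2-sided tests and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. A fold change is on the log2(value + 1) scale and understates the change of genes of low expression. The groups, the tests, the gene lists, the rule for named genes and the main alternatives were fixed before the data were examined. The library set as a term in the model, the fits in 1 library set only and the averaging of dapagliflozin 2 and 3 were chosen afterwards; the averaging was adopted after the counts with separate samples had been seen. Intervals of fold changes are 95% intervals of the fit. In the fit with the library set, the spread comes from all 14 samples, so low-read libraries are taken to vary like the others.

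Of 47 gene lists, 43 had at least 3 tested members and were tested with camera (preset correlation 0.01), again with an estimated correlation, and with fry, which asks whether a list moves in 1 direction on balance without comparing it with other genes. Calls were also adjusted over each list alone. Genes named in the text are 11 genes fixed by name, the 10 largest increases and decreases among called genes whose groups did not overlap, up to 4 called members of each list by smallest adjusted p, and 10 genes called in opposite directions by genotype and drug; predicted genes and clones were left out of the ranking. This rule ran on the pooled fit. Some genes that met it are not reported here. Genes outside it are named as chosen after their values were seen. Overlap with another gene's exons was taken from GRCm38 and marks a value as uncertain.

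Libraries were compared in pairs by the variance of their read numbers relative to what sampling gives, over genes with 20 to 99 reads and over all genes with at least 20. On simulated data the ratio was 0.981 for independent libraries and 0.610 where 40% of reads were shared. The limma steps were tested on simulated data of 12869 genes with the mean profile of each library set and the real read numbers. Every gene was given the same dispersion, 0.00257, taken from the m/m libraries. Over genes with at least 20 reads, high-read db/db vehicle pairs had ratios of 16.2 to 34.2 and m/m pairs 7.15 to 15.9. The shares below therefore hold for data quieter than the db/db vehicle libraries. Of genes changed 1.5-fold and 2-fold, 65% and 81% were recovered for db/db against m/m within library sets (38% and 67% pooled), with 0 of 12469 unchanged genes called. For dapagliflozin against vehicle 62% and 85% were recovered within sets (59% and 70% pooled), with 229 unchanged genes called (1471 pooled). A raised list of 30 genes was called for db/db against m/m and 0 of the other lists. Genes were simulated independently of each other, so this step does not show how camera behaves where genes vary together. In other splits of the real db/db vehicle and m/m samples, camera called up to 24 lists pooled and 19 within sets. Small camera p-values are therefore not calibrated by this step.

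Alternatives were other pseudocounts and filters, median-of-ratios and quantile scaling, array weights, the replicate number as a block, only the groups compared, each library left out, and, added after the data were seen, those named above, genes without opposite-strand overlap, and db/db vehicle 5 with dapagliflozin 1 left out. Analyses ran in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.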

Results

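Kidney mRNA was sequenced from male C57BLKS/J mice at 22 weeks of age in 3 groups of 5 libraries. Mice with the db/db genotype lack the signalling form of the leptin receptor and become obese and diabetic, and m/m mice of the same strain served as the non-diabetic controls. The m/m group and 1 db/db group received the vehicle, 0.5% methylcellulose. The other db/db group received 1 mg/kg dapagliflozin, an inhibitor of the proximal tubule glucose transporter SGLT2 (the product of Slc5a2), in the same vehicle. The title of the series names diabetic kidney disease, ferroptosis (an iron-dependent cell death by lipid peroxidation) and the hypoxia factor HIF1α with heme oxygenase HO1 (the product of Hmox1). The labels do not say whether the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be partly technical.

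The libraries fell into a high-read and a low-read set that crossed the groups. The 5 m/m libraries and db/db vehicle 1, 2 and 3 held 14.8 to 16.4 M reads in genes, and db/db vehicle 4 and 5 with the 5 dapagliflozin libraries held 1.60 to 2.29 M, a ratio of the set means of 8.20. The first principal component (81.5% of the variance) separated the sets and the next one (8.18%) spread the libraries within them. Pearson correlations across genes, which are not independent replicates, were 0.957 to 0.996 within a set and 0.781 to 0.840 across sets. Within the db/db vehicle group alone, 7859 of 12869 tested genes differed between the low-read and the high-read libraries (2418 higher and 5441 lower, limma adjusted p under 0.05). Counting precision followed depth: 3 reads amounted to 0.182 to 0.202 CPM in the high-read libraries and to 1.31 to 1.87 CPM in the low-read ones.

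Because of this split, each comparison below is given with all libraries pooled and with the library set as a term in the model, chosen after the sets were seen. The pooled fit was planned with 15 separate libraries. It was run on 14 samples, with dapagliflozin 2 and 3 averaged, a step adopted after the counts with separate samples had been seen. The pooled counts for dapagliflozin depended strongly on this step, as given under the processing. With the library set as a term, db/db vehicle is compared with m/m in the high-read libraries (3 against 5), and dapagliflozin with db/db vehicle in the low-read libraries (4 samples against 2). The words rose and fell refer to the fit within library sets unless pooling is named.

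**Figure D1:**
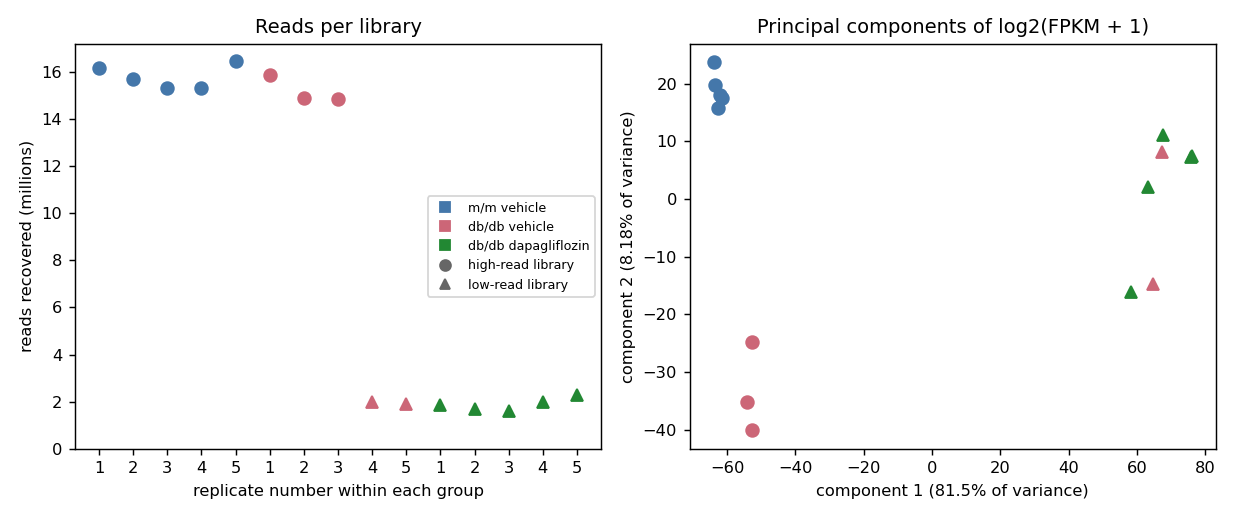
Reads recovered per library in M (left, by replicate number within each group) and the first 2 principal components of log2(FPKM + 1) (right, with their share of the variance), 1 point per library, coloured by group with circles for high-read and triangles for low-read libraries. The 8 high-read libraries hold 14.8 to 16.4 M reads and the 7 low-read libraries 1.60 to 2.29 M, and the first component parts them whatever their group.

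Comparing db/db with m/m kidneys under vehicle asks how the diabetic genotype changed the kidney transcriptome. The genes with the largest changes were ranked in the pooled fit, and their values are given within sets. A gene of fatty acid metabolism stood at the top of the ranked increases. Cyp4a14, a fatty acid omega-hydroxylase induced by PPARα, went from 2.72 ± 0.703 FPKM (SD, n = 5) to 409 ± 81.7 (n = 3), a log2 fold change of 6.78 (95% interval 6.46 to 7.11). At the other end, the organic anion transporter Slco1a1 fell from 224 ± 51.9 to 1.96 ± 0.615 FPKM (log2 fold change −6.23, 95% interval −6.64 to −5.82), and Kap, the androgen-regulated kidney protein of the proximal tubule, fell from 41608 ± 2422 to 2448 ± 1430 FPKM (log2 fold change −4.25). Kap took 2.41% to 2.77% of the reads in m/m libraries and 0.0793% to 0.246% in the 10 db/db libraries.

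Among the other genes with the largest pooled increases were the glucuronosyltransferases Ugt1a2 (5.53) and Ugt1a10 (3.90), whose values are uncertain because transcripts of this locus share their last exons, the vitamin D binding protein Gc (4.59), the betaine-homocysteine methyltransferase Bhmt (3.87), complement C3 (3.68) and the iron-sequestering injury marker Lcn2 (3.37), all as log2 fold changes within sets. Lcn2 went from 1.49 ± 0.669 to 43.9 ± 57.0 FPKM, and without db/db vehicle 1 the difference was 2.30 with an adjusted p of 0.0533, in a range of 0.00139 to 0.0533 over 28 alternatives. Nkx6-2 (2.34) overlaps a gene on the opposite strand and is uncertain, and Tmem200b rose by 0.93 within the high-read libraries against 3.11 with all libraries pooled. The largest pooled decreases besides Slco1a1 and Kap, given here within sets, were those of the organic anion transporter Slc22a7 (−5.07), Acsm3 (−4.71, overlapping another gene), the oxysterol hydroxylase Cyp7b1 (−4.09), the steroid dehydrogenase Akr1c14 (−4.08), Ldc1 (−3.92), Pzp (−3.74), the lysolipid transporter Mfsd2a (−3.62) and the amino acid transporter Slc7a13 (−3.60).

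Male-biased and androgen-dependent kidney genes fell together. Of 14 tested, 13 fell and 0 rose (the same counts adjusted over the list alone), with a median log2 fold change of −2.56 and an adjusted camera p of 2.49e-24, or adjusted p = 0.051 with an estimated correlation. Besides Slco1a1, Kap and Cyp7b1 they include Cyp4b1 (−2.24). Of 5 genes listed in advance as female-biased 3 rose and 2 fell. Among them were the prolactin receptor Prlr (1.54) and the steroid hydroxylase Cyp2a4, which fell from 446 to 60.2 FPKM (−2.90). The other gene that fell was Slc22a7, given above among the largest decreases. All mice were male, so the sex bias of the listed genes in this tissue was not tested. Any of them, those that rose as well as those that fell, may not belong on the list. The median of that list was 1.27, while its mean was −0.71 and its test pointed down (adjusted p = 0.461), or up after median-of-ratios scaling and quantile normalization.

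Fatty acid oxidation genes and PPARα targets rose: 25 of 32 rose and 4 fell (26 and 4 adjusted over the list alone), with a median of 0.69 and an adjusted p of 1.57e-05, or adjusted p = 0.468 with an estimated correlation. Acaa2, the mitochondrial thiolase, went from 101 to 312 FPKM (1.62) and the enoyl-CoA isomerase Eci1 from 89.6 to 216 (1.26). Gluconeogenesis genes (7 of 9 rose, 8 over the list alone, median 0.51, adjusted p = 0.0245, adjusted p = 0.385 with an estimated correlation) included G6pc (0.68) and Pck1 (0.86). The Pck1 increase missed the threshold without db/db vehicle 2 (0.72, adjusted p = 0.0802) or 3 (0.67, adjusted p = 0.104), within a range of 0.00303 to 0.104 over alternatives. It also missed after median-of-ratios scaling (0.64, adjusted p = 0.0977) and with the replicate number as a block (0.74, adjusted p = 0.0513). Of 16 glycolysis genes 10 rose and 0 fell, with or without adjustment over the list alone (median 0.33, adjusted p = 0.0203, adjusted p = 0.729 with an estimated correlation, 0.0503 after median-of-ratios scaling), as in Eno1 (1.17), Pkm (1.05) and Hk1 (0.68). Of the ketone body genes Acat1 (−1.12), Oxct1 (−1.19) and Bdh1 (−1.66), which use ketone bodies or interconvert them, fell. The median of the 6 in the list was −0.58 (1 rose and 3 fell, also over the list alone) and the test pointed down (adjusted p = 0.0203, adjusted p = 0.184 with an estimated correlation, 0.0773 after median-of-ratios scaling), against a mean of 0.46.

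Breakdown of branched-chain amino acids moved the other way: 10 of 18 genes fell and 0 rose (11 and 1 adjusted over the list alone; median −0.27, adjusted p = 1.66e-08, adjusted p = 0.184 with an estimated correlation). Isovaleryl-CoA dehydrogenase Ivd went from 184 to 70.6 FPKM (−1.38) and Hibadh fell by 0.53 on the log2 scale. Of 28 respiratory chain and ATP synthase subunits 16 rose and 0 fell (18 over the list alone; median 0.25, adjusted p = 0.0148, adjusted p = 0.757 with an estimated correlation), such as Cox5b (0.49). After median-of-ratios scaling this turned to 3 that rose and 6 that fell, with an adjusted p of 0.629. Of 19 cholesterol synthesis and uptake genes 6 fell and 3 rose (6 and 4 over the list alone). Their median was 0.04 but their mean −0.16, and the test pointed down (adjusted p = 0.0256, adjusted p = 0.757 with an estimated correlation, 0.134 after median-of-ratios scaling), with the lanosterol demethylase Cyp51 (−2.50, overlapping another gene) and Idi1 (−1.38) the clearest. Fatty acid synthesis genes went both ways, 5 up and 2 down of 16 (the same over the list alone; adjusted p = 0.666), with Elovl6 at 1.03 and Me1 at −1.37. Of 16 tricarboxylic acid cycle genes 5 rose and 0 fell (5 over the list alone; median 0.12, adjusted p = 0.442), against 0 and 3 after median-of-ratios scaling.

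Transporters and markers of nephron segments changed as well. Of 22 genes of renal glucose and sodium transport 14 rose and 2 fell, with or without adjustment over the list alone (median 0.42, adjusted p = 0.00499, adjusted p = 0.084 with an estimated correlation). Slc5a1, which encodes the glucose transporter SGLT1, went from 24.4 ± 3.01 FPKM (n = 5) to 48.3 ± 3.02 (n = 3), a log2 fold change of 0.96 (adjusted p = 2.82e-05). Slc5a2, the target of dapagliflozin, was at 287 ± 23.1 and 317 ± 94.1 FPKM (0.10, 95% interval −0.20 to 0.41, adjusted p = 0.6), but at 0.34 with an adjusted p of 0.0166 without db/db vehicle 1. Its sign turned without db/db vehicle 2 (−0.10, adjusted p = 0.561) and after median-of-ratios scaling (−0.12, adjusted p = 0.609). The adjusted p of Slc5a2 ranged from 0.0166 to 0.819 over alternatives. The fructose and mannose transporter Slc5a10 (1.69, overlapping another gene), the urate transporter Slc2a9 (1.05) and the epithelial sodium channel subunit Scnn1a (0.95) rose too. All 6 distal convoluted tubule markers rose (6 over the list alone; median 0.80, adjusted p = 0.00315, adjusted p = 0.369 with an estimated correlation), among them the thiazide-sensitive cotransporter Slc12a3 (1.02) and Trpm6 (0.81). Of 7 intercalated cell markers 6 rose (7 over the list alone; median 0.75, adjusted p = 0.0121, adjusted p = 0.468 with an estimated correlation), such as the proton pump subunit Atp6v1b1 (0.84), and the principal cell water channel Aqp2 rose by 0.87. Of 12 proximal tubule markers 6 fell and 1 rose (7 and 1 over the list alone; median −0.31, adjusted p = 1.5e-04, adjusted p = 0.385 with an estimated correlation), including the endocytic receptor megalin, Lrp2 (−0.74), and Acsm2 (−1.35). Of 12 podocyte markers 8 rose and 1 fell (8 and 3 over the list alone, adjusted p = 0.213), with nephrin, Nphs1, at 0.75.

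Genes of ferroptosis and of the HIF and heme pathways, the subject of the series title, changed one by one, while camera called 0 of their 5 fixed lists within sets as deposited, and HIF-1 targets alone after quantile normalization (up, adjusted p = 0.0105, or 0.139 with an estimated correlation). By fry, which does not compare a list with other genes, all 5 moved up within sets (adjusted p from 4.31e-06 for HIF-1 targets to 0.0205 for ferroptosis-promoting genes). After median-of-ratios scaling fry kept HIF-1 targets up (0.0179), turned ferroptosis-promoting genes down (0.00129) and called 0 of the other 3. Of 21 ferroptosis-promoting genes 6 rose and 1 fell (the same over the list alone; median 0.14, adjusted p = 0.924), and of 22 protecting genes 10 rose and 3 fell (11 and 3 over the list alone; median 0.20, adjusted p = 0.924). After median-of-ratios scaling these counts became 4 and 3, and 4 and 6. Acsl4, which loads membranes with polyunsaturated fatty acids, went from 9.70 ± 0.367 to 17.1 ± 4.96 FPKM (0.72, adjusted p = 0.00229), but was not called with all libraries pooled (0.31, adjusted p = 0.325, in a range of 3.70e-04 to 0.656 over alternatives). The lipoxygenase Alox15 fell from 7.05 to 0.340 (−2.56) while Alox12 rose (0.78). Among protecting genes the glutathione synthesis enzymes Gclm (−0.92) and Gclc (−0.92) fell and the cystine transporter chain Slc3a2 rose (0.59). The lipid peroxidase Gpx4 was at 331 ± 10.6 and 380 ± 17.5 FPKM (0.20, adjusted p = 0.0321; 0.18 pooled, adjusted p = 0.0584), which turned to −0.02 after median-of-ratios scaling and lost its call when any of 6 high-read libraries was left out. Those were m/m 1, 3, 4 and 5 (adjusted p 0.0551 to 0.0652) and db/db vehicle 1 (0.0762) and 2 (0.115), within a range of 0.00738 to 0.836 over alternatives. The cystine transporter Slc7a11 lay below the expression filter (0.0283 FPKM in m/m and 0.0734 in db/db vehicle libraries).

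Hif1a rose from 20.8 ± 1.1 to 30.4 ± 2.52 FPKM (0.52, 95% interval 0.37 to 0.68, adjusted p = 1.42e-04), after scaling too. With all libraries pooled the difference was −0.02 (adjusted p = 0.963), the low-read db/db vehicle libraries standing at 11.2 FPKM. Of 29 HIF-1 target genes 14 rose and 1 fell (15 and 1 over the list alone; median 0.35, adjusted p = 0.193), or 5 and 6 after median-of-ratios scaling. The kinase Pdk1 (1.84) and Eno1 rose and the prolyl hydroxylase subunit P4ha1 fell (−0.49). Of 8 HIF pathway components 4 rose (5 over the list alone, adjusted p = 0.442), against 2 that rose and 2 that fell after that scaling. Hmox1 was at 19.2 ± 4.25 and 24.8 ± 5.59 FPKM, a difference of 0.35 (95% interval −0.19 to 0.90) that did not pass the test (adjusted p = 0.292). Of 23 heme and iron genes 11 rose and 1 fell (the same over the list alone; adjusted p = 0.442), with transferrin, Trf (2.09), and ceruloplasmin, Cp (1.25, overlapping another gene), above and the metal transporter Slc39a8 (−0.90) below. Of 18 NRF2 targets 10 rose and 4 fell (11 and 4 over the list alone, adjusted p = 0.752), among them Gsta4 (1.5) and, downward, Sod1 (−0.64).

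Matrix genes were higher, and many injury genes rose one by one. Of 27 extracellular matrix and fibrosis genes 15 rose and 0 fell (16 over the list alone; median 0.82, adjusted p = 0.0137, adjusted p = 0.757 with an estimated correlation), including connective tissue growth factor Ccn2 (1.30) and collagen Col6a1 (1.42). Of 24 tubular injury genes 12 rose and 1 fell, also over the list alone (median 0.89). This list passed with the libraries pooled (adjusted p = 0.00476, adjusted p = 0.837 with an estimated correlation) and missed within sets (adjusted p = 0.0799), unless median-of-ratios scaling was used (0.00118, or 0.607 with an estimated correlation). The fibrinogen chain Fgg went from 3.87 to 26.3 FPKM (2.42), Sox4 rose (0.94) and the cytokine Il34 fell (−1.73), while the injury marker Havcr1 (KIM-1) was at 0.18 with a wide interval (−1.28 to 1.65, adjusted p = 0.857). Of 19 inflammatory signalling genes 9 rose and 0 fell, also over the list alone (median 0.57, adjusted p = 0.169), such as Tnfrsf1a (0.58). Of 5 neutrophil markers 4 rose (4 over the list alone; median 1.77, adjusted p = 0.153), and 0 of 10 macrophage markers were called (0 over the list alone; median 0.92, adjusted p = 0.866). Of 20 genes of the unfolded protein and integrated stress response 7 fell and 6 rose, also over the list alone (median −0.21, adjusted p = 0.0173, adjusted p = 0.581 with an estimated correlation, 0.0507 after median-of-ratios scaling). The chaperones Hspa5 (−0.69) and Hsp90b1 (−0.50) were among the former and the serine synthesis enzyme Phgdh (0.83) among the latter. In the renin-angiotensin system (3 rose and 2 fell of 9, also over the list alone, or 1 and 4 after that scaling; adjusted p = 0.102) angiotensin-converting enzyme Ace went from 88.7 to 12.8 FPKM (−2.74) and angiotensinogen, Agt, from 24.5 to 75.4 (1.58).

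**Figure D2:**
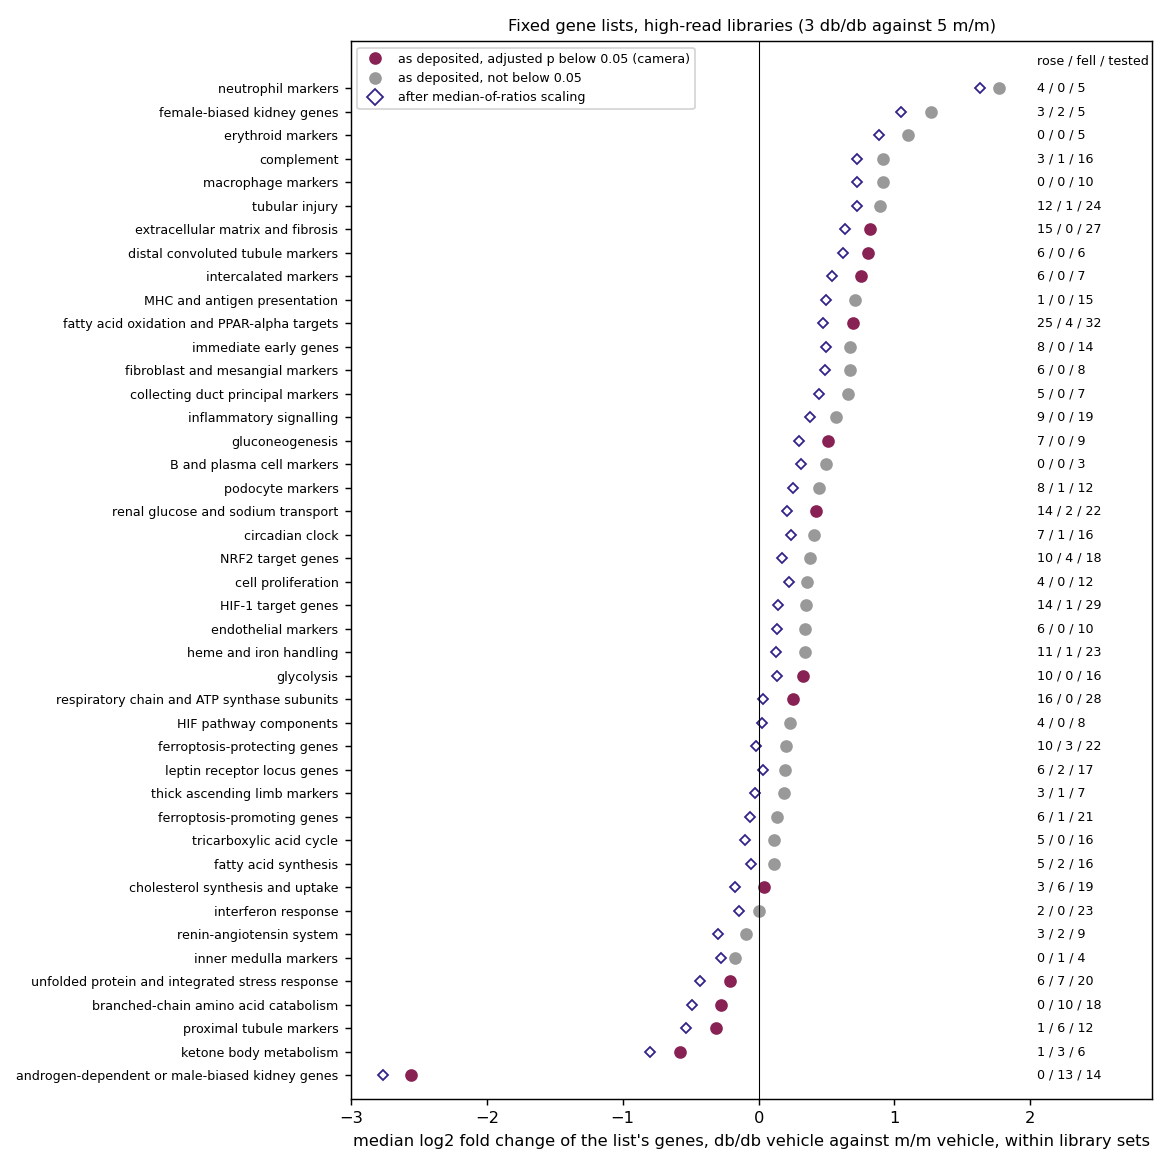
Median log2 fold change of each tested gene list fixed in advance, db/db vehicle against m/m vehicle within the high-read libraries (3 against 5), as deposited (filled, dark where the adjusted camera p is below 0.05) and after median-of-ratios scaling (open diamonds), with the numbers of genes that rose, fell and were tested at the right. Male-biased genes lie lowest at −2.56, and the medians of the ferroptosis-promoting, ferroptosis-protecting, thick ascending limb, tricarboxylic acid cycle, fatty acid synthesis, cholesterol and interferon lists change sign with the scaling.

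The db allele lies in Lepr. Lepr mRNA, which also comes from the short receptor forms that db leaves in place, was at 0.767 ± 0.138 and 0.828 ± 0.667 FPKM (log2 fold change −0.01, 95% interval −0.38 to 0.37). It was called with the libraries pooled only when db/db vehicle 1 was left out (−0.37, adjusted p = 0.0227, in a range of 0.0227 to 0.987 over alternatives).

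In total, limma called 4869 genes between db/db and m/m within library sets (3799 higher, 1070 lower) and 3170 with all libraries pooled (2097 higher, 1073 lower). Both fits called 2728 genes in the same direction and 0 in opposite ones, out of 5285 genes at an unadjusted p under 0.05 pooled and 6028 within sets. At least a 2-fold change was called for 454 genes within sets (275 higher, 179 lower) and 486 pooled, where leaving out db/db vehicle 2 or 3 raised the number to 796 or 748 (712 without vehicle 1). Of the genes called with all libraries pooled, 2557 had all 5 libraries of 1 group above those of the other. Over all genes tested, called or not, 24.6% were apart in this way, against 0.794% by chance. The excess of increases depended on scaling. The median of all tested genes was 0.16 within sets and −0.01 after median-of-ratios scaling, a shift of most genes by about that amount, and the share of calls that were higher went from 78.0% to 38.8% with it (1489 higher, 2349 lower) and to 47.6% with quantile normalization; pooled, it went from 66.2% to 38.6% and 34.9%. Camera called 14 of 43 lists within sets (8 up, 6 down) and 12 pooled. With an estimated correlation 0 held within sets, where fry called 32, and 1 held pooled, that of the male-biased genes (adjusted p = 0.0385). After median-of-ratios scaling camera called 16 lists within sets (13 up, 3 down), also those of tubular injury, inflammatory signalling (0.0104), complement (0.0439), immediate early genes (0.00393), fibroblasts (0.0103), principal cells (0.0248) and neutrophils (0.0147), and no longer those of glycolysis, ketone bodies, cholesterol, the respiratory chain and the stress response. With an estimated correlation 0 of these 16 held (lowest adjusted p 0.24). After quantile normalization camera called 20 lists within sets (17 up, 3 down), and 1 list passed with an estimated correlation (adjusted p = 0.0121).

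**Figure D3:**
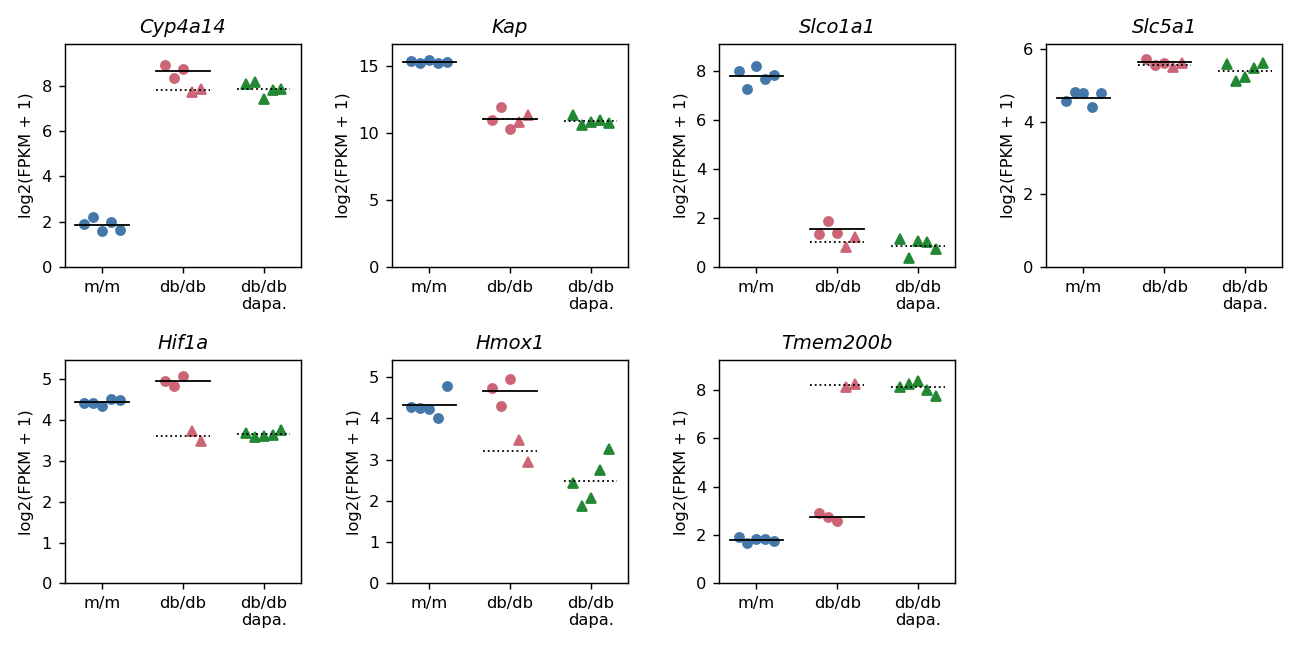
Expression of 7 named genes as log2(FPKM + 1) in each library, by group, with circles for high-read and triangles for low-read libraries and lines at the set means of each group (solid high-read, dotted low-read). Cyp4a14 is higher and Kap and Slco1a1 lower in every db/db library than in every m/m library, while Hif1a, Hmox1 and Tmem200b differ between the library sets of the db/db vehicle group.

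The comparison of dapagliflozin with vehicle in db/db kidneys asks which of these differences the drug moved. Within sets 36 genes were called. Tma16, a ribosome assembly factor, fell from 1.76 ± 0.0650 FPKM (SD, n = 2) to 0.254 ± 0.352 (n = 4), a log2 fold change of −1.18. The muscle ankyrin repeat gene Ankrd23 fell from 3.36 ± 0.156 to 0.594 ± 0.506 (−1.51), the acyl-CoA synthetase family member Slc27a3 from 2.46 ± 0.544 to 0.724 ± 0.417 (−1.02), and Eif4ebp3, a repressor of translation initiation, from 11 ± 0.722 to 5.13 ± 1.25 (−0.99). Hoxc11 rose from 1.97 ± 0.326 to 4.70 ± 1.22 FPKM and Ccdc183 from 2.23 ± 0.552 to 5.19 ± 1.32, each by 0.92. These 6 had adjusted p from 0.0232 to 0.0491 and each lost its call without db/db vehicle 4 (adjusted p 0.0779 to 0.235), without vehicle 5 (0.119 to 0.24) and without m/m 1 (0.0542 to 0.0765), in a range of 7.87e-04 to 0.437 over alternatives. Slc27a3, Hoxc11 and Ccdc183 lost it without each of most other libraries too, and all but Ankrd23 without dapagliflozin 4. The low values of Tma16, Ankrd23 and Slc27a3 may rest on few reads. In these low-read libraries 3 reads amounted to 1.31 to 1.87 CPM.

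The genes named in the title of the series did not pass the test within sets. The low-read libraries behind these values may have been counted with another strand setting, a candidate explanation weighed further below. The values may then not measure these mRNAs alone, so a missing call does not show that the drug left them unchanged. Hmox1 was at 8.46 ± 2.46 FPKM under vehicle (n = 2) and 5.42 ± 2.42 with dapagliflozin (n = 4), a difference of −0.61 (95% interval −1.26 to 0.03, adjusted p = 0.423). With all libraries pooled it fell by 1.48 on the log2 scale (adjusted p = 0.0439), against the mean that includes the high-read vehicle libraries at 24.8 FPKM. Hif1a was at 11.2 ± 1.42 and 11.7 ± 0.611 FPKM (0.06, 95% interval −0.13 to 0.25, adjusted p = 0.852; −0.76 pooled, adjusted p = 0.0654). Intervals of the difference were −0.22 to 0.11 for Gpx4, −0.35 to 0.41 for Acsl4, −0.25 to 0.48 for Slc5a2, the transporter that dapagliflozin inhibits, and −0.38 to 0.19 for Slc5a1. Those of the injury markers Havcr1 (−2.45 to 1.02) and Lcn2 (−2.46 to 2.0) were too wide to exclude a change of several fold. All these intervals, those of Hmox1 and Hif1a included, take the low-read libraries to vary like the high-read ones. They may therefore be too narrow. For this comparison within sets, 229 of 12469 unchanged genes were called in simulated data. The narrower intervals thus do not by themselves exclude a change either.

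Of 43 gene lists 0 were called by camera in either fit of the deposited values. Pooled, the lowest adjusted p was 0.19 (fry 0.128), and within sets it was 0.0769 for extracellular matrix genes (median −0.29, fry 0.953 at the lowest). That list alone was called within sets after median-of-ratios scaling (adjusted p = 0.0225, 0.969 with an estimated correlation) and after quantile normalization (0.0173, 0.996 with an estimated correlation). Within sets, 6 lists passed without db/db vehicle 5, 4 without dapagliflozin 5, 2 without db/db vehicle 3 or 4 or m/m 2 and 1 without m/m 1 or dapagliflozin 1, and pooled 2 passed without dapagliflozin 5 and 1 without db/db vehicle 4. Erythroid markers, a sign of blood, had a median of 1.28 (5 genes, 0 called, adjusted p = 0.099). Of the ferroptosis-promoting genes 0 were called within sets (median −0.02, adjusted p = 0.948), and so for the protecting genes (−0.05, adjusted p = 0.948), HIF pathway components (−0.04, adjusted p = 0.886), HIF-1 targets (−0.03, adjusted p = 0.799) and heme and iron genes (0.00, adjusted p = 0.886). Adjusted over the list alone, 1 HIF-1 target rose and 2 fell, and 1 heme and iron gene rose. Pooled, Ncoa4, the ferritinophagy receptor, was the 1 promoting gene called and fell by 0.58 (−0.25 within sets, adjusted p = 0.16), and Egln1, the HIF prolyl hydroxylase, fell by 0.42 (−0.23 within sets). Of the fatty acid synthesis list 2 of 16 rose within sets (2 rose and 1 fell over the list alone). They are the diacylglycerol acyltransferase Dgat1 (0.50, adjusted p = 0.0252) and the lipogenic regulator Thrsp (1.36, adjusted p = 0.0423), picked out after their values were seen, and both were lost without db/db vehicle 4 (adjusted p 0.181 for Dgat1 and 0.0865 for Thrsp), vehicle 5 (0.0841 and 0.237), m/m 1 or 2 or dapagliflozin 4 (0.0542 to 0.0941), among others, in a range of 0.00519 to 0.382 over alternatives.

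Libraries of different groups were closer to each other here than independent libraries should be. Over genes with 20 to 99 reads, db/db vehicle 5 and dapagliflozin 1 differed by 0.656 ± 0.0242 times the variance that sampling alone gives, dapagliflozin 2 and 3 by 0.675 times, db/db vehicle 4 and dapagliflozin 5 by 0.681 times and dapagliflozin 1 and 2 by 0.786 ± 0.0259 times, against 1.5 to 7.89 times for pairs of high-read libraries. Dapagliflozin 2 and 3 differed by less than the sampling noise (ratio 0.966 over all genes with at least 20 reads, chi-square p = 0.994) and were counted as 1 sample. Over the 109 genes with the most reads, however, their ratio was 7.59, so they were not copies of each other. Dapagliflozin 1 and 2 (1.58 over all genes with at least 20 reads) were kept as separate samples, so the n = 4 may overstate the independent samples. The 2 remaining pairs join libraries of different groups and were kept, although db/db vehicle 5 and dapagliflozin 1 were as close (0.954). Leaving out both of these libraries gave 8 calls within sets and 5648 pooled.

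With all libraries pooled limma called 850 genes (175 higher, 675 lower; 105 at least 2-fold), and 36 (17 higher, 19 lower; 8 at least 2-fold) within sets, where 1632 passed at an unadjusted p under 0.05. Both fits called 22. Of the 850, 598 (70.4%) also differed between the low-read and high-read libraries of the vehicle group, 596 in the same direction, where 7859 of all 12869 tested genes did. Of the pooled calls 489 had all libraries of 1 group above those of the other. Over all genes tested 5.66% were apart in this way, against 0.794% by chance for 10 independent libraries, which these are not. In the low-read libraries alone 1 gene was called (737 unadjusted), the ribosomal pseudogene Rps15a-ps5, named after its value was seen (−1.70, adjusted p = 0.0402). It is not among the 36, and 0 of the 36 were called in the low-read libraries alone, where the next adjusted p was 0.854. Camera called 5 lists there (adjusted p = 0.986 with an estimated correlation): extracellular matrix down (0.0115) and cholesterol (0.0381), proximal tubule (0.0381), intercalated (0.0038) and erythroid genes (0.0038) up. In simulated data with 12469 unchanged genes, the same fits called 1471 of them pooled and 229 within sets, more than the real counts. The simulated spread was taken from the m/m libraries, so these counts are not directly comparable with the real ones.

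The largest pooled calls, picked for their size, lay nearer to 0 within sets. The largest pooled increases, Gal3st4 (2.28), Ghrl (1.84), Cenpk (1.69, overlapping another gene), Ccr10 (1.62), Spopl (1.43), Hyls1 (1.31, overlapping another gene) and Nppa (1.19), stood at 0.52, 0.85, 0.36, 0.77, 0.35, 0.54 and 0.81. The largest pooled decreases, Eif1 (−1.85), Serpina3g (−1.57), Clec2d (−1.49), Swi5 (−1.47), Ndufs6 (−1.41), Rtl8a (−1.38) and F2r (−1.34), stood at −0.38, −0.97, −0.49, −0.31, −0.35, −0.38 and −0.46. Eif1, for instance, was at 202 FPKM in the high-read vehicle libraries, 36.4 in the low-read ones and 27.7 with dapagliflozin. Both counts depended on single libraries. The pooled count was 0 without dapagliflozin 4 (limma, 4758 genes unadjusted) and 119 without dapagliflozin 1. It was 5871 without db/db vehicle 4, 6633 without vehicle 5, 14 to 24 without vehicle 1, 2 or 3 and 28 to 49 without any 1 of the m/m libraries, which enter only through the shared spread. Within sets it was 126 without dapagliflozin 1, 110 without dapagliflozin 5, 1 without db/db vehicle 4, 3 without vehicle 5 and 5 to 22 without any other library, except 31 and 33 without dapagliflozin 2 or 3. Scaling moved the pooled share of increases from 20.6% to 43.8% (median-of-ratios, 548 genes) and that within sets from 47.2% to 55.1% (quantile).

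**Figure D4:**
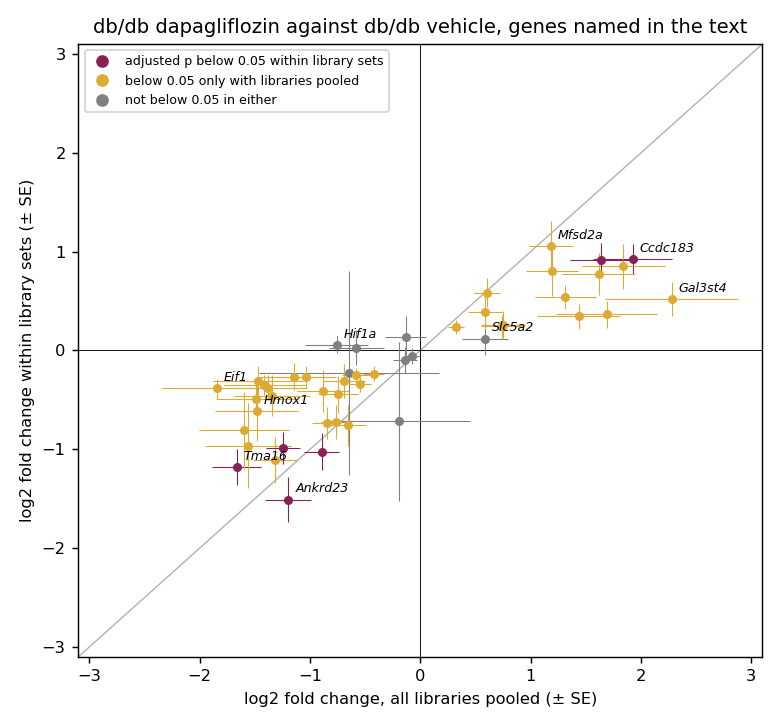
Log2 fold change of the genes named in the text, dapagliflozin against db/db vehicle, with all libraries pooled (horizontal) and within library sets (vertical), 1 point per gene with standard errors, coloured by where the adjusted p is below 0.05, and a line of equal values. Most pooled calls lie nearer to 0 within sets, such as Eif1 at −1.85 and −0.38, while Ankrd23 lies at −1.20 and −1.51.

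Dapagliflozin-treated db/db kidneys set against m/m kidneys show what stayed different under the drug. Lists were not tested in this comparison. Several of the genes most changed in db/db kidneys differed here too. Cyp4a14 was at 239 ± 20.2 FPKM (n = 4), higher than in m/m libraries by 6.88 on the log2 scale within sets, and Slco1a1 (−6.34), Kap (−4.38) and Mfsd2a (−2.57) were lower. Slc5a1 was higher by 0.87 (adjusted p = 0.00469), Hif1a by 0.58 (adjusted p = 0.00436) and Acsl4 by 0.75 (adjusted p = 0.0407). Hmox1 (−0.26, adjusted p = 0.695), Gpx4 (0.14, adjusted p = 0.371), Slc5a2 (0.22, adjusted p = 0.534), Lcn2 (3.14, adjusted p = 0.126), Havcr1 (−0.54, adjusted p = 0.771) and Lepr (0.13, adjusted p = 0.775) did not pass. Dapagliflozin and m/m libraries share no library set, so each of these values is the sum of the 2 other comparisons within sets. limma called 2264 genes in this way (1628 higher, 636 lower), or 1168 without db/db vehicle 5. Pooled, where group and library set cannot be told apart, it called 7657, with Hmox1 at −1.71 (adjusted p = 0.00191), Hif1a at −0.78 (adjusted p = 0.0304) and Slc5a2 at 1.00 (adjusted p = 0.00142). Scaling moved the share of increases within sets from 71.9% to 35.8% (median-of-ratios) and 46.5% (quantile).

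Genes moved by the genotype and in the opposite direction by dapagliflozin were rare. Mfsd2a fell from 22.3 ± 3.63 FPKM in m/m to 0.922 ± 0.551 in db/db kidneys and was at 3.57 ± 0.921 with dapagliflozin against 1.25 ± 0.841 in the low-read vehicle libraries. That is a log2 change of 1.05 (95% interval 0.52 to 1.59) which passed with all libraries pooled (1.18) but not within sets (adjusted p = 0.101). Ankrd23 (0.69, then −1.51) and Slc27a3 (0.60, then −1.02) passed both tests in both fits. However, the first step of Slc27a3 missed within sets without db/db vehicle 3 (0.55, adjusted p = 0.0503, in a range of 0.00178 to 0.148). That of Ankrd23 missed with a pseudocount of 0.1, within sets (1.13, adjusted p = 0.151) and pooled (1.41, adjusted p = 0.0661). The first step of both missed within sets after quantile normalization (0.31 and, for Ankrd23, 0.40). The later step of both missed without db/db vehicle 4 (adjusted p 0.115 and 0.235) or 5 (0.119). The related Ankrd1 was at 0.61 and then −0.73 (adjusted p = 0.0833 for the latter). Pooled, 79 genes were called in opposite directions (67 up then down, 12 down then up) and 86 in the same one, where independent lists would give 125 and 84.8. Within sets there were 7 (6 up then down) and 6, where independent lists would give 7.02 and 6.60. The pooled number was 363 without db/db vehicle 4, 650 without vehicle 5, 0 to 7 without any other vehicle or m/m library or dapagliflozin 4, and 14 without dapagliflozin 1. That within sets was 0 without db/db vehicle 4 or 5, 21 without dapagliflozin 1, 28 without dapagliflozin 5 and 2 to 4 without any other vehicle or m/m library or dapagliflozin 4.

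With all libraries pooled, both comparisons share the db/db vehicle libraries. Across genes, which are not independent replicates, the correlation of the fold changes was 0.607 pooled, and the covariance 0.248. Simulations of unchanged groups gave −0.468 and −0.0357 on average over 30 runs, but they hold no library sets and so are not the values of no change for these samples. With the vehicle libraries split between the comparisons, the correlation was 0.516 to 0.895 where vehicle 4 or 5 was set against m/m and −0.105 to −0.0609 where neither was. Within sets, where the comparisons use different db/db vehicle libraries, correlation and covariance were −0.08 and −0.01. Splitting the vehicle libraries between the comparisons gave 0 to 287 genes called in opposite directions, the latter with vehicle 4 and 5 set against m/m.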

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

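The test of shared reads and the odds ratio for genes opposite an abundant gene were chosen only after the result was seen; the thinning and the rank correlation were set before. Values far from the rest of their group were those whose gap to the nearest other value exceeded the 95% critical value of Dixon's test. This was met by 23 of 408 groups of values over 134 genes, or 5.64%, where chance gives about 5%. They fell in db/db vehicle 1 (5 values), dapagliflozin 5 (4), m/m 3 (3) and, with 1 or 2 each, other libraries.

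In the m/m group, Hmox1 was at 26.5 FPKM in replicate 5 (others 15.2 to 18.4) and Slc2a9 at 4.69 in the same library (3.58 to 3.88). Ivd was at 174 FPKM in replicate 3 (185 to 189), Ace at 104 (82.2 to 88.1) and Slc27a3 at 0.569 (0.968 to 1.11). Col6a1 was at 3.93 FPKM in replicate 1 (1.80 to 2.17) and H2-DMa at 3.37 (0.761 to 1.07). Per2 was at 4.99 FPKM in replicate 4 (1.99 to 2.78) and Ndufs6 at 114 (122 to 124).

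In db/db vehicle 1, Lepr was at 1.60 FPKM (others 0.150 to 0.457), Slc22a7 at 9.78 (1.00 to 2.11), Trf at 45.7 (12.1 to 19.4), Acat1 at 112 (142 to 149) and Rrm2 at 4.88 (2.12 to 2.78). In db/db vehicle 3, Slc2a9 was at 11.4 FPKM (7.87 to 8.49).

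In the dapagliflozin group, Havcr1 was at 8.33 FPKM in replicate 5 (others 0.242 to 0.849), Lcn2 at 48.7 (4.39 to 11.1) and Col6a1 at 10.2 (4.43 to 4.97), and this library had 15183 genes above 0 (14474 to 14561). Slc5a10 was at 709 FPKM in replicate 1 (604 to 619) and Per1 at 7.95 (5.35 to 5.68). The mean of replicates 2 and 3 stood apart for Gclm at 43.9 FPKM (51.1 to 52.5) and Prlr at 4.75 (4.02 to 4.14).

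The split into high-read and low-read libraries was weighed first. Lower depth alone is argued against as the cause of the 7859 genes that differed between the sets within the db/db vehicle group: with the high-read libraries thinned at random to 1.89 M reads, 81.8% were still called in the same direction, and the thinned libraries kept correlations of 0.972 to 0.980 among themselves. A candidate explanation is that the low-read libraries, made with a stranded kit, were counted with the opposite strand setting. Of 72 genes of low expression that lie opposite an abundant gene, 43.1% were at least 4-fold higher in the low-read libraries against 4.53% of 9242 others (odds ratio 15.9, 95% interval 9.54 to 26.3), and across genes the change followed the opposite gene's level by a rank correlation 0.316 higher (95% interval 0.274 to 0.357) where exons overlap than where they do not. Only 61.3% of the 31 raised genes had more reads than the gene opposite, so a mixture of settings or of library kinds stays open, and no biological explanation was tested.

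Pairs of low-read libraries were weighed second. Between db/db vehicle 5 and dapagliflozin 1 the variance was 0.656 times that of sampling, below 1 by more than its standard error of 0.0242 allows for independent libraries, while the lowest of 28 high-read pairs was at 1.5. Reads present in both libraries of a pair may account for this: in simulated data a share of 40% gave 0.610 and none gave 0.981. Over the 131 genes with the most reads the ratio for the same pair was 7.67, which argues against the libraries being copies of each other. Whether samples were mixed, or reads assigned to more than 1 library, stays open, and reads shared between vehicle and dapagliflozin libraries would make the differences and intervals within sets too small; no biological explanation was tested.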

How the results depend on the processing

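The library set as a term and with it every value given within sets, the fits in 1 library set, the omission of a close pair and the omission of genes overlapping opposite-strand exons were chosen after the data were seen. The averaging of dapagliflozin 2 and 3 was adopted after the counts with separate samples had been seen. Separate samples, as planned, were then kept as an alternative. The other pooled settings were planned, but their values rest on this averaging. Where a cause is not named, the cause was not tested.

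For db/db against m/m, of 2901 values of 97 named genes pooled, 2838 kept direction and side of the threshold, 42 lost the call, 9 gained it and 3 reversed, those of Hif1a: 0.50 with array weights and 0.52 in the high-read libraries alone or with the library set as a term, against −0.02. Within sets 2667 of 2707 kept both and 28 lost the call, and Gpx4 reversed to −0.023 after median-of-ratios scaling. For dapagliflozin, 965 of 1494 values of 50 genes kept both pooled (496 lost the call, 0 reversed) and 1274 of 1394 within sets (105 lost it, 0 reversed).

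With the library set as a term the numbers of called genes were 4869 for db/db against m/m, 36 for dapagliflozin against vehicle and 2264 for dapagliflozin against m/m, with 8 genes at least 2-fold changed by dapagliflozin and 7 changed in opposite directions. With array weights the pooled numbers were 5983 for db/db against m/m, 8532 for dapagliflozin (2225 at least 2-fold) and 2565 in opposite directions, but within sets 1 for dapagliflozin (1 at least 2-fold), 0 in opposite directions and 1 list. The high-read libraries alone gave 6605 for db/db against m/m, and the low-read libraries alone gave 1 for dapagliflozin (1 at least 2-fold) and 5 lists. With dapagliflozin 2 and 3 as separate samples, as planned, 4751 genes were called for dapagliflozin (972 at least 2-fold) and 311 in opposite directions. With their average these pooled numbers were 850 (105 at least 2-fold) and 79. Within sets, separate samples gave 13 at least 2-fold and 2 lists. Leaving out both db/db vehicle 5 and dapagliflozin 1 gave 5648 (1321 at least 2-fold) and 500 in opposite directions, and within sets 8, 0 and 5 lists, with 1385 for dapagliflozin against m/m.

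With only the groups compared in the fit, limma called 0 genes for dapagliflozin (0 at least 2-fold, 3628 at an unadjusted p under 0.05), 0 in opposite directions, and within sets 0 (0 at least 2-fold, 972 unadjusted) and 3 lists. Fewer samples then give the spread, but whether this is why the calls were lost was not tested. Median-of-ratios scaling gave 548 for dapagliflozin (56 at least 2-fold), and within sets 1 list, that of extracellular matrix. Quantile normalization gave 49 in opposite directions, and within sets 13 at least 2-fold and the same 1 list. Without a filter, 50 genes were at least 2-fold changed by dapagliflozin, and within sets 222 were called (17 at least 2-fold) with 38 in opposite directions. A mean of at least 1 FPKM left 5 at least 2-fold within sets. A pseudocount of 0.1 gave 1003 genes at least 2-fold changed in db/db (853 within sets) and 246 by dapagliflozin (22 within sets), and 0.5 gave 176 and, within sets, 14, as a smaller pseudocount widens fold changes of low genes. With an estimated correlation camera called 1 list for db/db against m/m (0 within sets), and fry called 19 (32 within sets). Splitting the vehicle libraries gave 0 to 287 genes in opposite directions.

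Same-numbered samples of different groups did not deviate together (correlations of deviations from group means −0.466 to 0.163, and −0.724 to 0.381 from means of group and library set), so no pairing by number is seen. With the number as a block 2995 genes were called for dapagliflozin (794 at least 2-fold) and 170 in opposite directions. Within sets the block gave 1 (1 at least 2-fold), 1 in opposite directions, and 1289 for dapagliflozin against m/m.

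Leaving out 1 library at a time gave 2273 to 3763 genes for db/db against m/m (382 to 796 at least 2-fold), 0 to 6633 for dapagliflozin (0 to 1385) and 6940 to 8097 for dapagliflozin against m/m, with 0 to 650 in opposite directions and 11 to 16 and 0 to 2 lists. Within sets it gave 3370 to 5222 (398 to 555), 1 to 126 (1 to 22) and 1168 to 2668, with 0 to 28 in opposite directions and 14 to 18 and 0 to 6 lists. The number for dapagliflozin by limma was 0 pooled without dapagliflozin 4 (4758 unadjusted), 6633 and 5871 without db/db vehicle 5 and 4, 119 without dapagliflozin 1, and 14 to 49 without any other vehicle or m/m library. Within sets it was 1 without db/db vehicle 4, 3 without vehicle 5, 126 and 110 without dapagliflozin 1 and 5, and 5 to 22 without any other vehicle or m/m library or dapagliflozin 4. The 2-fold changes in db/db numbered 796 and 748 without db/db vehicle 2 and 3, and dapagliflozin against m/m within sets gave 1168 without db/db vehicle 5. Where a group in 1 library set keeps a single library, that library is assumed to vary like the others.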

Other observations

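The fits within library sets and the tests of pathways from the deposited annotation were chosen after the data were seen; the pooled fit, the gene lists, the splits and the test of chromosome 4 were set before their results. Between db/db and m/m kidneys within library sets, camera called 26 of 313 pathways of 10 to 300 genes (16 down, 10 up), of which butanoate metabolism alone passed with an estimated correlation (adjusted p = 0.0337). Degradation of valine, leucine and isoleucine held 48 tested genes, of which 19 fell and 9 rose (adjusted p = 2.15e-05, 0.897 with an estimated correlation), and butanoate metabolism held 24, of which 11 fell and 4 rose (adjusted p = 9.07e-06). Propanoate metabolism (12 of 32 fell, 4 rose), sphingolipid metabolism (12 of 41 fell, 8 rose) and protein processing in the endoplasmic reticulum (41 of 158 fell, 33 rose, adjusted p = 2.27e-04) pointed down too, at 0.897 to 0.933 with an estimated correlation. Genes of the ribosome (73 of 134 rose, 1 fell, median 0.29, adjusted p = 6.19e-04) and of oxidative phosphorylation (61 of 114 rose, 4 fell, median 0.26, adjusted p = 6.19e-04) were higher, by little more than the median of all tested genes (0.16), and at 0.933 with an estimated correlation. The HIF-1 signalling pathway was called as well (44 of 93 rose, 3 fell, median 0.29, adjusted p = 0.0363), but not with an estimated correlation (adjusted p = 0.933). For dapagliflozin against vehicle 0 pathways were called by camera within sets (lowest adjusted p 0.949).

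Of other lists fixed in advance, those below were not called by camera between db/db and m/m kidneys within sets, although immediate early genes (adjusted p = 0.00393) and complement genes (adjusted p = 0.0439) were after median-of-ratios scaling, where 0 lists held with an estimated correlation (lowest adjusted p 0.24). Of 16 circadian clock genes 7 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.22), with Per1 (1.15) and Per2 (1.16) among them. Of 14 immediate early genes 8 rose and 0 fell, also over the list alone (adjusted p = 0.0596), such as Fosl2 (0.97) and Jun (0.67). Of 10 endothelial markers 6 rose (6 over the list alone, adjusted p = 0.191), or 2 rose and 2 fell after median-of-ratios scaling, with Eng at 0.82. Of 23 interferon genes 2 rose (0 over the list alone, adjusted p = 0.231), of 16 complement genes 3 rose and 1, Cfb (−0.62), fell (also over the list alone, adjusted p = 0.516), and of 4 inner medulla markers 1, Aqp4 (−1.45), fell (1 over the list alone, adjusted p = 0.0908).

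Linked alleles around Lepr on chromosome 4 are one hypothesis for the genotype difference. Genes within 10 Mb of Lepr in the reference assembly GRCm38 were called as often as others, 27 of 95 (28.4%) against 24.8% pooled (odds ratio 1.20, 95% interval 0.740 to 1.91, Fisher's exact p = 0.406) and 41.1% against 38.1% within sets (1.13, 0.731 to 1.74). An enrichment of calls near Lepr was therefore not seen, and the intervals exclude a large one. The 95 genes of the window are too few to make up much of the calls (3099 lay elsewhere, pooled). The test therefore cannot decide whether linkage is a main source of the calls. Strain differences elsewhere stay open, as untested.

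Other splits of the same samples into groups of the same sizes were counted, the real one included. For db/db against m/m, 1 of 100 splits gave as many genes as the real 3170 (highest other 1) and 1 of 100 as many 2-fold changes as 486 (highest other 1), and within sets 1 of 56 for 4869 (highest other 5) and 1 of 56 for 454 (highest other 4). Each share lies under 0.05, which argues against chance in how these samples were grouped. These are the smallest shares the splits can give. The splits take libraries as independent, although the labels do not say whether they came from separate animals. Chance stays open for the number of lists: 34 of 100 splits gave at least 12 (highest other 24) and 19 of 56 at least 14 within sets (highest other 19). For dapagliflozin against m/m 1 of 100 gave 7657 (highest other 4176), and the 4 splits drawn with all low-read samples on 1 side had a median of 3678, which points to the library sets.

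For dapagliflozin against vehicle chance cannot be excluded for the pooled counts of genes: 7 of 100 splits gave at least 850 genes (highest other 7560), and 8 of 100 at least 105 2-fold changes (highest other 1446). For lists the real number is 0, so 100 of 100 are as large whatever the data (highest other 20), which decides nothing. The 4 splits whose smaller group held all 3 high-read samples had a median of 6659 and include the highest, so library sets alone give more genes than the drug groups do; the value within sets was 36. In the 11 splits with all high-read samples in the larger group, as in the real one, the median was 1.0 and the highest 5853. Within sets, 15 splits are too few for a share under 0.05. The real 36 genes and 8 2-fold changes stood beside highest others of 1701 and 260, with 6 and 5 splits as large, which points to a structure among the low-read samples. For the 0 lists all 15 are as large whatever the data (highest other 13), which decides nothing. For genes changed in opposite directions 2 of 100 splits gave at least 79 (highest other 5492, which points to a structure of the samples too). This share follows how many genes a split calls at all, and 79 lies below the 125 that independent lists of these sizes would give, so no excess of opposite changes over chance is shown.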
